A study of Arabidopsis thaliana with 48 samples.

How the data were processed

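RNA sequencing of 48 libraries from whole seedlings (40 mg fresh weight per sample, RNeasy extraction and TruSeq RNA v2 libraries per the labels) was analysed, in 16 groups of 3 replicates given by genotype and collection time per the labels. Per the submitters' processing notes, reads were aligned with Bowtie2 to TAIR10. The aligner's version is not given in the sources used here. The deposited tables hold the authors' expected counts for 35386 coding-sequence targets per library, in the format of the eXpress quantifier, with unique and total read counts beside them. The expected counts per the file headers are estimated counts that divide reads shared between targets, and the deposited unique counts are reads that fit 1 target. These units were tested against the values in the files, and the lengths of 99.99% of targets were multiples of 3.

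Expected counts were summed per locus and rounded, which gave 27416 loci, of which 26719 had a name in the TAIR10.1 annotation. That build differs from the TAIR10 of the labels, so it was used for gene names and the order of loci alone, and no coordinates are given. At 5480 loci, reads are shared with other loci, and such genes are marked where named. The total count per library ran from 5441501 to 10817328. Unique counts made up 56.3% to 57.8% of it, the 10 most abundant genes 6.19% to 12.2% and plastid loci 0.0259% to 0.0444%. Loci with counts numbered 20482 to 21604 per library. The counts are reads without molecular identifiers, so intervals would cover counting error only, and the spread between replicates was used instead.

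Tests used R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Genes were kept with edgeR's filterByExpr at a minimum count of 10 (19404 genes), libraries were scaled by TMM, and 1 quasi-likelihood model with 16 group means was fitted to all 48 libraries (residual degrees of freedom 32, common coefficient of variation 12.3%). Contrasts were each mutant against Col-0 at each time (14 comparisons), ZT18 against ZT6 in Col-0, and the difference of each mutant's effect between the times (the interaction). All tests were two-sided, p values were adjusted by Benjamini-Hochberg within each contrast, and the threshold was 0.05. CPM are expected counts scaled to library size by edgeR, and log2 CPM for list tests used a prior count of 2. The lists were 21 sets of genes with known roles (391 loci), written before the data were examined, and the plastid- and mitochondria-encoded genes. They were tested with limma's camera at a preset correlation of 0.01 and with an estimated correlation. Similarity of profiles was set against simulated unchanged groups that share controls.

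The genes named in the text follow a rule also fixed before the data were examined. It took the mutated loci in every library, and per comparison the 5 largest and 5 smallest log2 fold changes (10 for parp1x2x3, srt1x2 and the times in Col-0) among genes past the threshold with a mean log2 CPM of at least 1 and no overlap between 3 and 3 libraries, which chance gives for 10% of genes. It added the 10 genes per mutant with the largest smaller change among those changed the same way at both times, the 5 smallest adjusted p per interaction, and up to 4 genes per list. The genes beside SRT1 and those shared by all mutants were chosen after their values were seen.

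The fit of all 48 libraries was tried on data simulated at the depth of the parp1-2 comparison. At ZT6 it recovered 29 of 67 genes changed 1.5-fold, 53 of 67 changed 2-fold and 61 of 66 changed 4-fold, with 5 false calls among 148. At ZT18 it recovered 38, 52 and 66, with 13 false calls among 169. Alternatives were RLE scaling, no filter on low counts, a term for the replicate number, unique counts, a fit of only the groups compared, DESeq2, an estimated correlation, a minimum average log2 CPM of 3 for similarity, and each library left out in turn. Chosen after seeing the data were the mean of parp1-2, parp2-1, parp3-1 and srt2-1 as reference in place of Col-0 and a fit without the srt1-4 and srt1x2 ZT6 libraries. Total counts per target and effective lengths were not used here, and isoforms were not analysed.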

Results

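RNA was sequenced from 2-week-old seedlings of Arabidopsis thaliana of 8 genotypes, collected by day at zeitgeber time 6 (ZT6) and by night at zeitgeber time 18 (ZT18) under 12 h of light and 12 h of darkness. The genotypes were the wild type Col-0, mutants of genes for poly(ADP-ribose) polymerases (parp1-2, parp2-1, parp3-1 and the combined parp1x2x3), and mutants of genes for sirtuins (heterozygous srt1-4, srt2-1, and srt1x2, a cross of srt2-1 with heterozygous srt1-4). Both enzyme families use up NAD, and each mutant was compared with Col-0 at each time to ask which transcripts differ when these enzymes are mutated. Each of the 16 groups had 3 libraries, of 5441501 to 8690864 counts at ZT6 and 6824912 to 10817328 at ZT18. Levels below are means ± SD of counts scaled to library size (CPM) with n = 3, and log2 values are fold changes ± SE. Adjusted p values come from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over 19404 genes. The labels do not state whether the 3 libraries of a group came from separately grown seedlings, so a p-value measures only the spread between these samples, which may be technical.

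The mutated loci were examined in every library before any other gene. At4g02390, the locus of parp1-2, had 9.66 ± 1.13 CPM in Col-0 at ZT6 and 9.10 ± 0.556 CPM at ZT18. Its transcript fell to 2.35 ± 0.868 and 2.56 ± 1.02 CPM in parp1-2 (log2 -2.0 ± 0.23 and -1.85 ± 0.22, adjusted p = 5.6e-07 and 9.32e-07) and to 2.29 ± 0.746 and 1.37 ± 0.241 CPM in parp1x2x3 (log2 -2.11 ± 0.24 and -2.73 ± 0.23, adjusted p = 9.84e-08 and 1.17e-10). At2g31320, the locus of parp2-1, had 15.7 ± 2.48 and 19.6 ± 1.23 CPM in Col-0 at ZT6 and ZT18. It was not lower in the libraries labelled parp2-1, with 19.7 ± 7.18 and 22.9 ± 1.64 CPM (adjusted p = 0.524 and 0.588), nor in those labelled parp1x2x3, with 19.0 ± 1.11 and 16.7 ± 1.75 CPM (adjusted p = 0.453 and 0.644). The annotation of TAIR10.1 names At4g02390 PARP2 and At2g31320 PARP1, the reverse of the line names. At5g22470, the locus of parp3-1, had 0 or 1 counts in every library, so its loss was not detectable at this depth.

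SRT1 (AT5G55760), the locus of srt1-4, was not lower in the libraries labelled srt1-4. It rose there from 9.08 ± 1.32 to 26.8 ± 4.43 CPM (log2 1.57 ± 0.17, adjusted p = 5.16e-10) at ZT6 and from 7.39 ± 0.68 to 40 ± 1.82 CPM (log2 2.43 ± 0.16, adjusted p = 1.44e-13) at ZT18. In the libraries labelled srt1x2 it had 6.11 ± 0.390 CPM at ZT6 (log2 -0.56 ± 0.19, adjusted p = 0.0167) and 6.42 ± 0.490 CPM at ZT18 (log2 -0.20 ± 0.18, adjusted p = 0.632). SRT2 (AT5G09230), the locus of srt2-1, had 18.9 ± 1.81 and 18.7 ± 2.82 CPM in Col-0 at ZT6 and ZT18. It was near absence in srt2-1, with 3 and 5 counts over the 3 libraries (0.153 ± 0.158 and 0.201 ± 0.158 CPM, adjusted p = 8.03e-20 and 1.82e-20), and in srt1x2, with 4 counts and 1 count (0.188 ± 0.0693 and 0.0325 ± 0.0563 CPM, adjusted p = 3.16e-20 and 2.39e-21). A transcript level does not show whether a functional protein was made, and the lines parp2-1, parp3-1, parp1x2x3, srt1-4 and srt1x2 are named below as labelled.

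**Figure D1:**
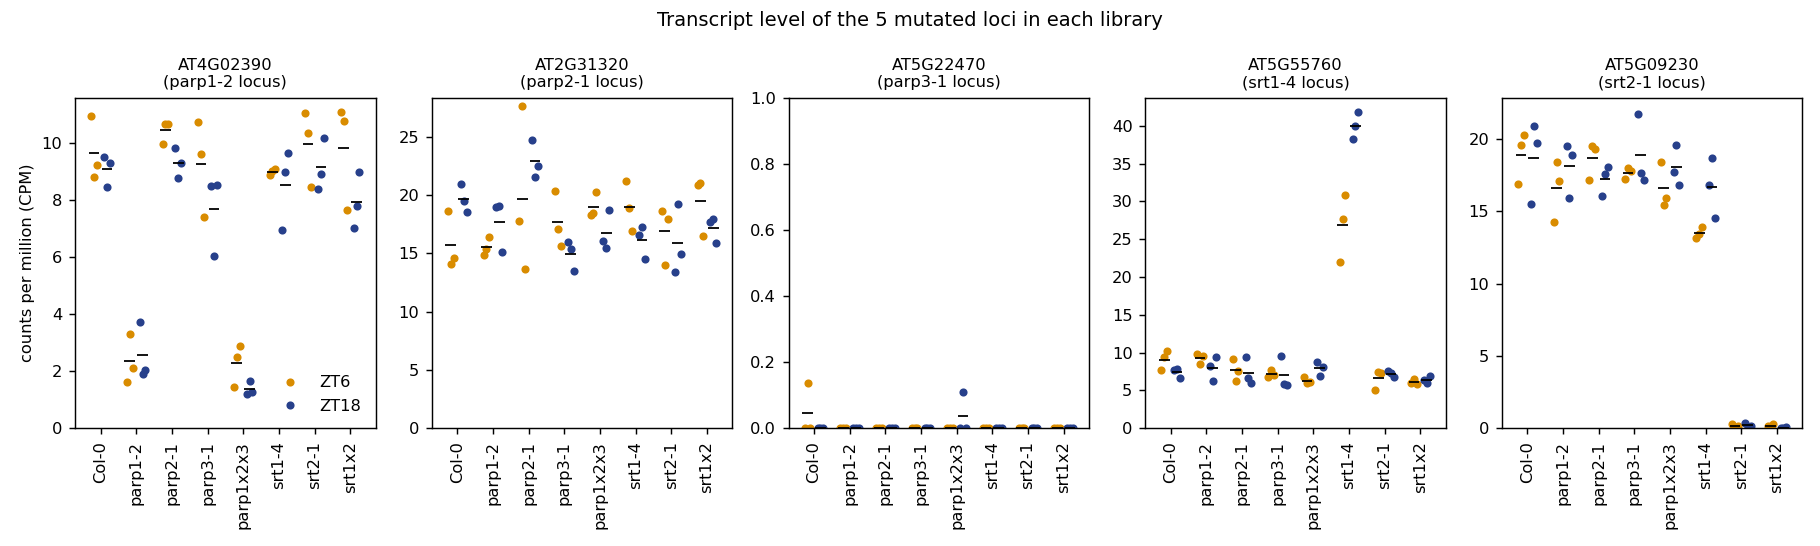
Transcript level (CPM) of each mutated locus in every library of the 8 genotypes, with points for the 3 libraries of a group (orange ZT6, blue ZT18) and black bars for their means. SRT2 had 18.9 CPM in Col-0 and 0.153 CPM in srt2-1 at ZT6, whereas SRT1 was higher in srt1-4 (26.8 CPM) than in Col-0 (9.08 CPM).

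In Col-0, the comparison of ZT18 with ZT6 shows the daily rhythm against which the mutants are set. The clock gene RVE2 (AT5G37260) rose from 4.88 ± 1.26 to 511 ± 49.8 CPM (log2 6.72 ± 0.21, adjusted p = 1.07e-25). LHY (AT1G01060), a morning gene of the clock, rose from 5.58 ± 0.67 to 84.1 ± 18.1 CPM (log2 3.91 ± 0.28, adjusted p = 1.93e-14). The day-expressed clock gene GI (AT1G22770) fell from 173 ± 6.39 to 1.92 ± 0.743 CPM (log2 -6.55 ± 0.19, adjusted p = 5.73e-26). PRR7 (AT5G02810) fell from 279.7 ± 9.42 to 2.29 ± 0.813 CPM (log2 -6.98 ± 0.22, adjusted p = 1.07e-25). CCA1 (AT2G46830) fell from 44.8 ± 6.42 to 7.74 ± 0.112 CPM (log2 -2.53 ± 0.24, adjusted p = 6.24e-11). The transcript of the light-harvesting protein LHCB2.1 (AT2G05100) fell from 4287 ± 317 to 71.6 ± 11.3 CPM (log2 -5.91 ± 0.33, adjusted p = 1.5e-17). BT2 (AT3G48360), which responds to low sugar, rose from 15.1 ± 6.49 to 663 ± 85.5 CPM (log2 5.47 ± 0.30, adjusted p = 9.91e-18). SEN1 (AT4G35770), also raised by low sugar, rose from 5.67 ± 0.742 to 169 ± 60.4 CPM (log2 4.89 ± 0.45, adjusted p = 2.61e-11). Of the genes of starch breakdown, BAM3 (AT4G17090) rose from 161 ± 8.88 to 672 ± 60.7 CPM (log2 2.06 ± 0.14, adjusted p = 1.81e-15). DPE2 (AT2G40840) fell from 394 ± 16.6 to 96.2 ± 5.05 CPM (log2 -2.03 ± 0.09, adjusted p = 4.0e-20).

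Counted over all genes, 6949 changed between ZT18 and ZT6 in Col-0, 3396 higher and 3553 lower at ZT18, of which 628 and 1222 differed at least 2-fold. Of the lists of genes with a known role, the photosynthesis list was lower at night, with 1 of 29 measured genes higher and 23 lower, as many as adjusted over the list alone (camera, adjusted p = 1.84e-19, and adjusted p = 0.293 with an estimated correlation). The list for abscisic acid, drought and cold had 3 of 27 measured genes higher and 21 lower, as many as adjusted over the list alone (adjusted p = 1.44e-05, and adjusted p = 0.654 with an estimated correlation). Cell division genes were lower, with 11 of 13 measured genes lower, as many as adjusted over the list alone (adjusted p = 0.00055, and adjusted p = 0.436 with an estimated correlation), among them CDKB2;1 (AT1G76540) (log2 -0.65 ± 0.13, adjusted p = 0.000142). The clock list had 9 of 32 measured genes higher and 18 lower, as many as adjusted over the list alone (adjusted p = 0.00076, and adjusted p = 0.346 with an estimated correlation). The phosphate starvation list had 4 of 9 measured genes lower, or 6 lower adjusted over the list alone (adjusted p = 0.0335, and adjusted p = 0.346 with an estimated correlation), with SPX1 (AT5G20150) falling from 24.4 ± 4.24 to 2.63 ± 0.61 CPM. The phosphate starvation list lost its call without Col-0 ZT18 replicate 1 (adjusted p up to 0.0539) or without Col-0 ZT6 replicate 1 (0.0796). Over the mutants, 38 of 308 list tests passed the threshold, and 0 of them did with an estimated correlation, where 11 had an unadjusted p under 0.05.

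The same small set of genes differed from Col-0 in nearly every mutant. Against Col-0, 13 genes changed the same way in at least 6 of the 7 mutants at both times, 12 higher and 1 lower, and 10 of them did so in all 7. In 10 simulated sets of unchanged groups, which call few genes, the highest was 0. At ZT18 21 genes were called in all 7 mutants, and calls repeated below, as for GI and TPS8, may reflect Col-0. AT3G01345, of unknown function, had 282 ± 19.1 CPM in Col-0 at ZT6 and 304 ± 15.7 CPM at ZT18, but group means of 0.0325 to 13.3 CPM in the mutants. ESM1 (AT3G14210), which steers glucosinolate breakdown, had 240.1 ± 12.5 and 118 ± 37.3 CPM in Col-0 and 335 to 597 CPM in the mutants. PLDGAMMA2 (AT4G11830), a phospholipase D whose reads are shared with related loci, had 47.8 ± 3.51 and 19.1 ± 1.96 CPM in Col-0 and 75.0 to 116 CPM in the mutants. The proton pump HA8 (AT3G42640) had 7.33 and 4.97 CPM in Col-0 and 14.2 to 22.0 CPM in the mutants, and AT5G51410, a LUC7-like gene, had 9.98 and 9.37 CPM against 22.7 to 28.4 CPM. The receptor-like kinases AT4G03230 and AT4G29990 had 3.89 and 0.381 CPM in Col-0 at ZT6 and at least 10.5 and 2.03 CPM in every mutant group. FLC (AT5G10140), a repressor of flowering whose reads are shared with related loci, rose in all mutants but srt1-4, from 1.44 ± 0.445 CPM in Col-0 at ZT6 and 1.95 ± 0.668 CPM at ZT18 to at most 6.84 CPM. MRD1 (AT1G53480) was seen at 13.9 ± 1.66 and 19.2 ± 2.33 CPM in Col-0 and at 0.0406 to 0.97 CPM in parp2-1, parp3-1, parp1x2x3 and srt2-1. Without 1 library, 9 to 13 genes were shared. With only the groups compared fitted it was 3, AT3G01345, PLDGAMMA2 and AT5G51410. In that fit FLC was called in 5 mutants at ZT6 (lost in parp2-1, adjusted p = 0.124) and lost its ZT18 call in all 6 (0.0983 to 0.326). AT4G03230 lost it in 6 mutants (0.0695 to 0.159) and AT4G29990 in 4 (0.0545 to 0.107). FLC also lost its ZT18 call in parp3-1 without Col-0 replicates 1, 2 or 3 or parp3-1 replicates 1 or 3, in parp1-2 without its replicate 3 and in srt2-1 without its replicate 1 (0.0608 to 0.223), and in parp3-1 with no low-count filter (0.0528) and without all srt1-4 and srt1x2 ZT6 libraries (0.0547).

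**Figure D2:**
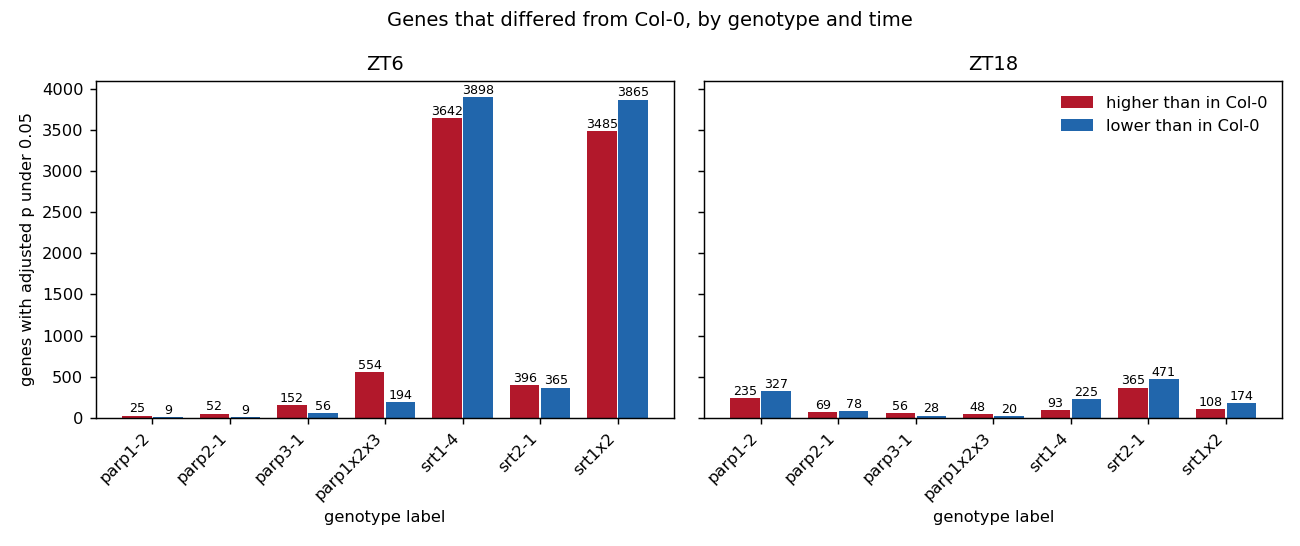
Number of genes with an adjusted p under 0.05 against Col-0 in each mutant, higher (red) and lower (blue), with 1 panel for ZT6 and 1 for ZT18 and 3 libraries per group. The libraries labelled srt1-4 and srt1x2 had 3642 and 3485 genes higher and 3898 and 3865 lower at ZT6, the tallest bars.

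In parp1-2 at ZT6, AT5G05200, which encodes a predicted protein kinase, fell from 243 ± 7.21 to 47.8 ± 7.81 CPM (log2 -2.35 ± 0.11, adjusted p = 5.57e-19). ATPMEPCRB (AT4G02330), a pectin methylesterase gene near At4g02390, fell from 13.1 ± 4.26 to 2.04 ± 0.727 CPM (log2 -2.73 ± 0.41, adjusted p = 7.99e-05). FLC rose from 1.44 ± 0.445 to 6.33 ± 1.87 CPM (log2 2.11 ± 0.30, adjusted p = 4.68e-05). QQS (AT3G30720), a gene found in Arabidopsis alone that affects starch content, rose from 0.591 ± 0.288 to 4.88 ± 2.14 CPM (log2 3.07 ± 0.57, adjusted p = 0.0042). Plastid-encoded genes were higher as a set, median log2 0.16, with 0 of 44 measured genes past the threshold with edgeR or DESeq2, 2 higher at an unadjusted p under 0.05 and 0 adjusted over the list alone (camera, adjusted p = 0.0498, and adjusted p = 0.938 with an estimated correlation). In all, 34 genes changed, 25 higher and 9 lower. The number was 22 without Col-0 replicate 2, and 20 and 63 without parp1-2 replicates 2 and 3, 19 with only the groups compared fitted and 53 with DESeq2. It was 1095 with other mutants in place of Col-0. QQS and the plastid-encoded list lost the call in 1 or more of the fits without Col-0 replicate 1 (adjusted p up to 0.386) or replicate 2 (0.362) or without parp1-2 replicate 2 (0.509). The same held for 1 or more of these calls with no low-count filter (0.221).

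In parp1-2 at ZT18, AT5G05200 fell from 174 ± 7.91 to 16.5 ± 2.04 CPM (log2 -3.41 ± 0.12, adjusted p = 1.62e-23). As at ZT6, ATPMEPCRB fell from 7.87 ± 1.51 to 1.47 ± 0.421 CPM (log2 -2.39 ± 0.43, adjusted p = 0.00147). QQS rose from 0.373 ± 0.0717 to 5.54 ± 1.76 CPM (log2 3.87 ± 0.59, adjusted p = 0.000136). ESM1 rose to 550 ± 85 CPM (log2 2.22 ± 0.18, adjusted p = 6.33e-11). The light-harvesting gene LHCB1.2 (AT1G29910) rose from 635 ± 131 to 1148 ± 98.7 CPM (log2 0.85 ± 0.21, adjusted p = 0.0223). LHCB3 (AT5G54270) rose from 212 ± 36.1 to 396 ± 84.9 CPM (log2 0.90 ± 0.25, adjusted p = 0.0377). The photosynthesis list had 4 of 29 measured genes higher, or 10 higher adjusted over the list alone (camera, adjusted p = 4.84e-06, and adjusted p = 0.938 with an estimated correlation). The hexose transporter gene STP1 (AT1G11260) fell from 289 ± 95.6 to 134 ± 34.4 CPM (log2 -1.11 ± 0.21, adjusted p = 0.00349). The sugar-repressed SEN5 (AT3G15450) fell from 811 ± 250.3 to 414 ± 86.6 CPM (log2 -0.97 ± 0.22, adjusted p = 0.0139). The flavonoid list had 3 of 18 measured genes higher, or 6 higher and 1 lower adjusted over the list alone (adjusted p = 0.0038, and adjusted p = 0.938 with an estimated correlation). In it, GSTF12 (AT5G17220) and DFR (AT5G42800) rose by log2 1.48 ± 0.37 and 1.12 ± 0.29. The list for oxidative and mitochondrial stress had 2 of 20 measured genes lower, or 3 lower adjusted over the list alone (adjusted p = 0.00548, and adjusted p = 0.938 with an estimated correlation). The catalase gene CAT2 (AT4G35090) in it was at log2 -0.53 ± 0.12. LHCB1.2, LHCB3, STP1, SEN5, GSTF12, DFR and CAT2 (AT4G35090) lost the call in 1 or more of the fits without Col-0 replicate 1 (adjusted p up to 0.184) or replicate 2 (0.256) or without parp1-2 replicate 1 (0.0903) or replicate 3 (0.257). Such losses occurred with unique counts (0.173) or with only the groups compared fitted (0.162) too.

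The ZT18 count of parp1-2 was 562 genes, 235 higher and 327 lower. It was 112, 55 and 1427 without Col-0 replicates 1, 2 and 3, and 255 and 41 without parp1-2 replicates 1 and 3, and 13 with only the groups compared fitted and 967 with DESeq2. The figure was 82 with other mutants in place of Col-0. At both times 23 genes of parp1-2 changed the same way, 18 higher and 5 lower, against 0.303 and 0.152 for independent calls, and 10 with other mutants in place of Col-0. AT5G05200, ATPMEPCRB and QQS were among them. The effect of parp1-2 differed between the times in 13 genes by an interaction test, among them AT5G05200 (log2 difference -1.05 ± 0.15, adjusted p = 0.000736) and TPS8 (AT1G70290), a trehalose phosphate synthase gene that shares reads with another locus (log2 difference -1.15 ± 0.19, adjusted p = 0.00762). The interaction count was 7 and 5 without Col-0 ZT6 replicates 1 and 3, 3, 2 and 41 without parp1-2 ZT6 replicates 1, 2 and 3, 2, 5 and 170 without Col-0 ZT18 replicates 1, 2 and 3, and 7 and 4 without parp1-2 ZT18 replicates 2 and 3, 73 with DESeq2 and 8 with unique counts. With only the groups compared fitted, edgeR called 0 genes, where 1998 had an unadjusted p under 0.05. AT5G05200 and TPS8 lost the call in 1 or more of the fits without parp1-2 ZT6 replicate 2 (adjusted p up to 0.0524). Further losses came with only the groups compared fitted (0.0555).

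The libraries labelled parp2-1 differed from Col-0 at both times in AT2G44970, an alpha/beta-hydrolase gene. It fell from 30.7 ± 8.97 to 9.9 ± 1.26 CPM (log2 -1.63 ± 0.15, adjusted p = 1.69e-09) at ZT6. At ZT18 it fell from 34.7 ± 2.58 to 12.1 ± 1.61 CPM (log2 -1.52 ± 0.14, adjusted p = 9.31e-10). FLC rose from 1.44 ± 0.445 to 4.89 ± 1.33 CPM (log2 1.75 ± 0.31, adjusted p = 0.00231) at ZT6. At ZT18 it rose to 5.55 ± 0.22 CPM (log2 1.48 ± 0.28, adjusted p = 0.00336). FKF1 (AT1G68050), a light receptor of the clock output, fell from 31.3 ± 5.79 to 18.1 ± 3.61 CPM (log2 -0.78 ± 0.17, adjusted p = 0.0219) at ZT6. As a set, the photosynthesis genes were higher at ZT6, median log2 0.19, with 0 of 29 measured genes past the threshold with edgeR or DESeq2, 2 higher and 1 lower at an unadjusted p under 0.05 and 0 adjusted over the list alone (camera, adjusted p = 0.0118, and adjusted p = 0.971 with an estimated correlation). The list of root markers was lower as a set, median log2 -0.65, with 0 of 15 measured genes past the threshold with edgeR or DESeq2, 1 lower at an unadjusted p under 0.05 and 0 adjusted over the list alone (adjusted p = 0.0343, and adjusted p = 0.938 with an estimated correlation). In all, 61 genes changed at ZT6, 52 higher and 9 lower. That number was 32 and 24 without Col-0 replicates 2 and 3, and 30 without parp2-1 replicate 1, 27 with only the groups compared fitted, 94 with DESeq2 and 40 with unique counts. It was 5 with other mutants in place of Col-0. FLC, FKF1, the photosynthesis list and the root markers list lost the call in 1 or more of the fits without Col-0 replicate 1 (adjusted p up to 0.0843), replicate 2 (0.122) or replicate 3 (0.21) or without parp2-1 replicate 1 (0.178) or replicate 3 (0.156). Calls were also lost with only the groups compared fitted (0.159).

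By night, GI, at its daily low, fell further in the libraries labelled parp2-1, from 1.92 ± 0.743 to 0.368 ± 0.183 CPM (log2 -2.37 ± 0.46, adjusted p = 0.00464). PLDGAMMA2 rose to 75 ± 1.71 CPM (log2 1.98 ± 0.11, adjusted p = 8.77e-16). The jasmonate list was lower as a set, median log2 -0.36, with 0 of 25 measured genes past the threshold with edgeR or DESeq2, 7 lower at an unadjusted p under 0.05 and 0 adjusted over the list alone (camera, adjusted p = 0.00934, and adjusted p = 0.938 with an estimated correlation). At ZT18 147 genes changed, 69 higher and 78 lower. That count was 24 without Col-0 replicate 1, and 70, 61 and 44 without parp2-1 replicates 1, 2 and 3, 8 with only the groups compared fitted and 236 with DESeq2. This became 10 with other mutants in place of Col-0. Over both times 19 genes changed the same way, 16 higher and 3 lower, against 0.185 and 0.0362 for independent calls, and 5 with other mutants in place of Col-0. The effect differed between the times in 60 genes, led by TPS8 (log2 difference -1.13 ± 0.19, adjusted p = 0.00849) and the zinc finger gene ATCTH (AT2G25900) (-1.14 ± 0.19, adjusted p = 0.00849). This number was 20 and 6 without Col-0 ZT6 replicates 2 and 3, 13 without parp2-1 ZT6 replicate 2, 4 and 33 without Col-0 ZT18 replicates 1 and 2, and 6, 30 and 5 without parp2-1 ZT18 replicates 1, 2 and 3, 261 with DESeq2, 39 with unique counts and 7 with only the groups compared fitted. GI and the jasmonate list lost the call in 1 or more of the fits without Col-0 replicate 1 (adjusted p up to 0.109) or without parp2-1 replicate 2 (0.105) or replicate 3 (0.0831).

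The libraries labelled parp3-1 nearly lacked AT5G62620, a galactosyltransferase gene, which fell from 9.83 ± 1.88 to 0.975 ± 1.04 CPM (log2 -3.36 ± 0.38, adjusted p = 2.02e-07) at ZT6. At ZT18 it went from 14.7 ± 2.33 to 0.0915 ± 0.159 CPM. SEN5 rose from 133 ± 23.9 to 343 ± 90.08 CPM (log2 1.36 ± 0.23, adjusted p = 0.000471) by day. FLC rose from 1.44 ± 0.445 to 5.42 ± 1.08 CPM (log2 1.89 ± 0.31, adjusted p = 0.000284). AT3G01345 varied among these libraries, with 13.3 ± 20.8 CPM at ZT6. The plastid-encoded genes were lower as a set at ZT6, median log2 -0.18, with 1 of 44 measured genes lower, as many as adjusted over the list alone (camera, adjusted p = 0.0169, and adjusted p = 0.938 with an estimated correlation). That gene was ATCG00470 (log2 -0.99 ± 0.19, adjusted p = 0.00335). At ZT6 208 genes changed, 152 higher and 56 lower. The count was 72 and 55 without Col-0 replicates 2 and 3, and 109, 130 and 96 without parp3-1 replicates 1, 2 and 3, 100 with only the groups compared fitted and 20 with other mutants in place of Col-0. The plastid-encoded list and ATCG00470 lost the call in 1 or more of the fits without Col-0 replicate 3 (adjusted p up to 0.52). The same held for 1 or more of these calls with only the groups compared fitted (0.11).

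By night, GI in the libraries labelled parp3-1 fell from 1.92 ± 0.743 to 0.255 ± 0.138 CPM (log2 -2.75 ± 0.46, adjusted p = 0.000575). PRR7 fell from 2.29 ± 0.813 to 0.359 ± 0.0729 CPM (log2 -2.57 ± 0.48, adjusted p = 0.00253). The dawn gene CCA1 rose from 7.74 ± 0.112 to 18.6 ± 3.47 CPM (log2 1.26 ± 0.25, adjusted p = 0.00602). Plastid-encoded genes were again lower as a set, median log2 -0.19, with 0 of 44 measured genes past the threshold with edgeR or DESeq2, 6 lower at an unadjusted p under 0.05 and 0 adjusted over the list alone (camera, adjusted p = 0.0105, and adjusted p = 0.938 with an estimated correlation). The list for salicylic acid and immunity had a median log2 of 0.21, with 0 of 29 measured genes past the threshold with edgeR or DESeq2, 4 higher and 1 lower at an unadjusted p under 0.05 and 0 adjusted over the list alone (adjusted p = 0.0323, and adjusted p = 0.938 with an estimated correlation). In all 84 genes changed, 56 higher and 28 lower. This was 34 without Col-0 replicate 1, and 50, 45 and 40 without parp3-1 replicates 1, 2 and 3, 19 with only the groups compared fitted and 130 with DESeq2. This became 36 with other mutants in place of Col-0. GI, PRR7, CCA1, the plastid-encoded list and the salicylic acid and immunity list lost the call in 1 or more of the fits without Col-0 replicate 1 (adjusted p up to 0.0626), replicate 2 (0.112) or replicate 3 (0.187) or without parp3-1 replicate 1 (0.0935), replicate 2 (0.849) or replicate 3 (0.0633). Such losses occurred with only the groups compared fitted (0.199) or with unique counts (0.189) too.

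Across both times, 25 genes of the libraries labelled parp3-1 changed the same way, 21 higher and 4 lower, against 0.439 and 0.0808 for independent calls, and 12 with other mutants in place of Col-0. BT2, which rises at night in Col-0, had an effect of parp3-1 that differed between the times (log2 difference -2.35 ± 0.37, adjusted p = 0.00112), as did TPS8 (-1.36 ± 0.19, adjusted p = 0.000198), ATCTH (-1.17 ± 0.19, adjusted p = 0.00249) and PLDGAMMA2 (1.11 ± 0.15, adjusted p = 0.000163). The interaction test gave 61 such genes. The count was 96, 35 and 18 without Col-0 ZT6 replicates 1, 2 and 3, 25 without parp3-1 ZT6 replicate 2, 31 and 24 without Col-0 ZT18 replicates 1 and 2, and 30, 27 and 25 without parp3-1 ZT18 replicates 1, 2 and 3, 210 with DESeq2 and 29 with only the groups compared fitted. PLDGAMMA2 lost its call with unique counts (adjusted p = 0.831).

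In the libraries labelled parp1x2x3 at ZT6 several genes of low sugar were higher. BT2 rose from 15.1 ± 6.49 to 156 ± 37 CPM (log2 3.38 ± 0.29, adjusted p = 1.48e-10). SEN5 rose from 133 ± 23.9 to 532 ± 87.6 CPM (log2 1.99 ± 0.23, adjusted p = 2.01e-07). DIN10 (AT5G20250) rose from 178 ± 45.7 to 518 ± 151 CPM (log2 1.54 ± 0.24, adjusted p = 6.33e-05). STP1 rose from 66.7 ± 6.18 to 145 ± 14.4 CPM (log2 1.12 ± 0.22, adjusted p = 0.00143). The starvation list had 5 of 20 measured genes higher, or 7 higher and 2 lower adjusted over the list alone (camera, adjusted p = 0.00627, and adjusted p = 0.938 with an estimated correlation). The NAD transporter gene NDT1 (AT2G47490) fell from 33.8 ± 3.18 to 23.5 ± 1.78 CPM (log2 -0.52 ± 0.11, adjusted p = 0.00187). MYB34 (AT5G60890), a regulator of indole glucosinolates, fell from 44.3 ± 2.68 to 26.4 ± 2.51 CPM (log2 -0.74 ± 0.16, adjusted p = 0.00332). AT5G62620 fell as in parp3-1, from 9.83 ± 1.88 to 1.88 ± 1.36 CPM (log2 -2.47 ± 0.35, adjusted p = 8.44e-06). ATPMEPCRB fell as in parp1-2, from 13.1 ± 4.26 to 3.87 ± 2.22 CPM (log2 -1.82 ± 0.37, adjusted p = 0.0018).

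Genes of abscisic acid, drought and cold were lower as a set in these libraries at ZT6, with 1 of 27 measured genes higher and 2 lower, or 2 higher and 4 lower adjusted over the list alone (camera, adjusted p = 0.00967, and adjusted p = 0.938 with an estimated correlation). RD29A (AT5G52310), raised by drought and cold, fell from 244 ± 115 to 81.2 ± 24.5 CPM (log2 -1.58 ± 0.44, adjusted p = 0.0329). The ethylene list had 2 of 19 measured genes higher and 1 lower, or 4 higher and 1 lower adjusted over the list alone (adjusted p = 0.0381, and adjusted p = 0.938 with an estimated correlation). One was the regulator EIN3 (AT3G20770) (log2 0.37 ± 0.09, adjusted p = 0.0156). Flavonoid genes were lower as a set, median log2 -0.48, with 0 of 18 measured genes past the threshold with edgeR and 1 with DESeq2, 2 higher and 6 lower at an unadjusted p under 0.05 and 2 higher and 4 lower adjusted over the list alone (adjusted p = 0.0235, and adjusted p = 0.938 with an estimated correlation). The whole count at ZT6 was 748 genes, 554 higher and 194 lower, 162 of them at least 2-fold. It was 494 and 269 without Col-0 replicates 2 and 3, and 399 and 373 without parp1x2x3 replicates 2 and 3, 348 with only the groups compared fitted and 110 with other mutants in place of Col-0. The abscisic acid, drought and cold list, RD29A, the ethylene list, EIN3 and the flavonoid and anthocyanin list lost the call in 1 or more of the fits without Col-0 replicate 1 (adjusted p up to 0.21), replicate 2 (0.0663) or replicate 3 (0.299) or without parp1x2x3 replicate 2 (0.164) or replicate 3 (0.139). Further losses came with only the groups compared fitted (0.112).

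At ZT18 the libraries labelled parp1x2x3 again had lower ATPMEPCRB, which fell from 7.87 ± 1.51 to 1.64 ± 0.158 CPM (log2 -2.23 ± 0.40, adjusted p = 0.00167). AT5G62620 fell from 14.7 ± 2.33 to 1.33 ± 0.606 CPM (log2 -3.41 ± 0.31, adjusted p = 7.36e-10). ESM1 rose to 504 ± 71.3 CPM (log2 2.09 ± 0.18, adjusted p = 1.85e-10). GI went from 1.92 ± 0.743 to 0.073 ± 0.126 CPM. The jasmonate list was lower as a set, median log2 -0.33, with 0 of 25 measured genes past the threshold with edgeR or DESeq2, 6 lower at an unadjusted p under 0.05 and 0 adjusted over the list alone (camera, adjusted p = 0.00199, and adjusted p = 0.938 with an estimated correlation). The DNA damage response list was higher, median log2 0.16, with 0 of 23 measured genes past the threshold with edgeR or DESeq2, 3 higher at an unadjusted p under 0.05 and 0 adjusted over the list alone (adjusted p = 0.0321, and adjusted p = 0.838 with an estimated correlation). In all 68 genes changed, 48 higher and 20 lower. This was 31 without Col-0 replicate 1, and 44, 41 and 40 without parp1x2x3 replicates 1, 2 and 3, 20 with only the groups compared fitted and 108 with DESeq2. This became 8 with other mutants in place of Col-0. The jasmonate list and the DNA damage response list lost the call in 1 or more of the fits without Col-0 replicate 1 (adjusted p up to 0.0594) or replicate 2 (0.102) or without parp1x2x3 replicate 2 (0.0663). Calls were also lost with no low-count filter (0.061).

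Over both times 28 genes of the libraries labelled parp1x2x3 changed the same way, 22 higher and 6 lower, against 1.37 and 0.2 for independent calls, and 8 with other mutants in place of Col-0. The effect on BT2 differed between the times by the interaction test (log2 difference -3.54 ± 0.37, adjusted p = 8.01e-08), and so did those on TPS8 (-1.95 ± 0.19, adjusted p = 4.04e-08) and TPS11 (AT2G18700) (-2.33 ± 0.26, adjusted p = 4.71e-07). In all 537 genes had an effect that differed between the times, 105 with a higher and 432 with a lower log2 fold change at ZT18. The number was 204 without Col-0 ZT6 replicate 3, 287 and 276 without parp1x2x3 ZT6 replicates 2 and 3, 317 and 279 without Col-0 ZT18 replicates 1 and 2, and 310 and 353 without parp1x2x3 ZT18 replicates 1 and 3, and 219 with only the groups compared fitted.

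The libraries labelled srt1-4 and srt1x2 differed most from Col-0 at ZT6. There several genes of sugar shortage were far above their Col-0 levels. SEN1 (AT4G35770) rose from 5.67 ± 0.742 to 775 ± 192 CPM (log2 7.08 ± 0.47, adjusted p = 2.69e-15) in srt1-4. In srt1x2 it rose to 777 ± 145 CPM (log2 7.09 ± 0.47, adjusted p = 2.45e-15). SEN5 rose to 2344 ± 226 and 2317 ± 332 CPM, DIN10 to 2285 ± 423 and 2010.5 ± 356 CPM, and STP1 to 901 ± 134 and 834 ± 119 CPM. ASN1 (AT3G47340), of asparagine synthesis, rose from 26.4 ± 2.65 to 909 ± 218 CPM (log2 5.10 ± 0.49, adjusted p = 4.67e-11) in srt1x2. The starvation list had 11 of 20 measured genes higher and 6 lower, or 12 higher and 6 lower adjusted over the list alone in srt1-4 (camera, adjusted p = 0.0409, and adjusted p = 0.938 with an estimated correlation). In srt1x2 it had 11 of 20 measured genes higher and 6 lower, as many as adjusted over the list alone and was not called (adjusted p = 0.0676, and adjusted p = 0.938 with an estimated correlation). The starch and sugar starvation list lost its call without srt1-4 replicate 2 (adjusted p = 0.0525).

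Clock genes of the morning were lower and those of the evening higher in the same libraries at ZT6. CCA1 fell from 44.8 ± 6.42 to 2.47 ± 0.411 CPM (log2 -4.17 ± 0.29, adjusted p = 8.43e-15) in srt1-4. In srt1x2 it fell to 1.91 ± 0.318 CPM (log2 -4.56 ± 0.31, adjusted p = 5.42e-15). PRR9 (AT2G46790) fell from 60 ± 11 to 5.7 ± 0.942 CPM (log2 -3.38 ± 0.23, adjusted p = 3.36e-15) in srt1-4 and to 3.97 ± 1.75 CPM in srt1x2. LNK1 (AT5G64170) fell from 112 ± 4.54 to 24.1 ± 2.18 CPM (log2 -2.21 ± 0.14, adjusted p = 7.93e-16) and to 20.6 ± 2.14 CPM. TOC1 (AT5G61380), an evening gene, rose from 44.5 ± 4.45 to 139 ± 14.3 CPM (log2 1.65 ± 0.13, adjusted p = 2.05e-13) in srt1-4. In srt1x2 it rose to 156 ± 12.2 CPM (log2 1.81 ± 0.13, adjusted p = 1.67e-14). Of 17 clock genes with a known phase, 8 of the 9 morning genes were lower and 7 of the 8 evening genes higher past the threshold in each genotype. Over the whole clock list there were 10 of 32 measured genes higher and 15 lower, as many as adjusted over the list alone in srt1-4 and 10 of 32 measured genes higher and 16 lower, or 10 higher and 17 lower adjusted over the list alone in srt1x2. The list was not called as a set in srt1-4 (camera, adjusted p = 0.36, and adjusted p = 0.971 with an estimated correlation) or srt1x2 (adjusted p = 0.357, and adjusted p = 0.971 with an estimated correlation).

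**Figure D3:**
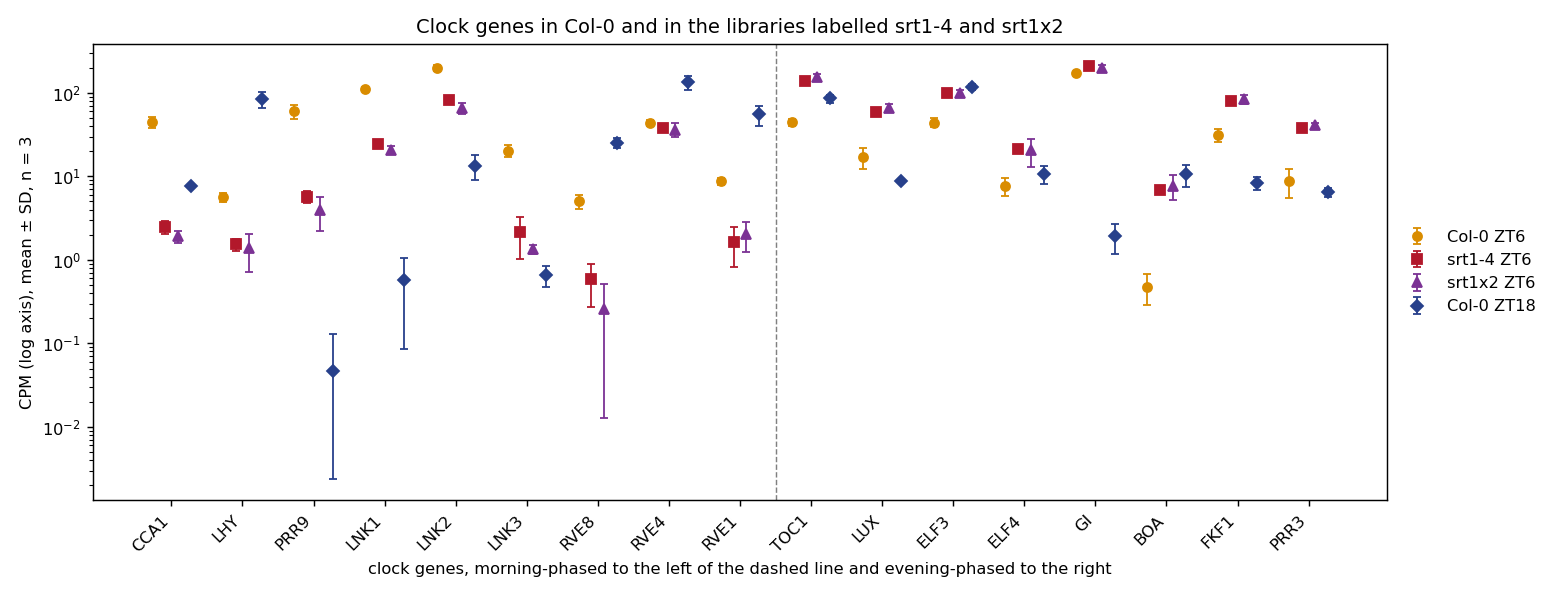
Transcript level (CPM, log axis) of 17 clock genes as means with SD of 3 libraries in Col-0 at ZT6 and ZT18 and in the libraries labelled srt1-4 and srt1x2 at ZT6, with morning genes left of the dashed line. The morning gene CCA1 lies at 44.8 CPM in Col-0 and 2.47 CPM in srt1-4 at ZT6, and the evening gene TOC1 at 44.5 and 139 CPM.

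Several genes of pigments and photosynthesis were lower in the libraries labelled srt1-4 and srt1x2 at ZT6. CHS (AT5G13930), the entry enzyme of flavonoid synthesis, fell from 205 ± 36.1 to 40 ± 7.16 CPM (log2 -2.35 ± 0.23, adjusted p = 6.7e-11) in srt1-4. In srt1x2 it fell to 36.6 ± 15 CPM (log2 -2.47 ± 0.23, adjusted p = 2.57e-11). The flavonoid list had 1 of 18 measured genes higher and 15 lower, as many as adjusted over the list alone in srt1-4 (camera, adjusted p = 7.69e-07, and adjusted p = 0.305 with an estimated correlation). The same list had 1 of 18 measured genes higher and 12 lower, as many as adjusted over the list alone in srt1x2 (adjusted p = 3.07e-06, and adjusted p = 0.305 with an estimated correlation). GUN4 (AT3G59400), of chlorophyll synthesis, fell from 339 ± 12.6 to 98.5 ± 3.83 CPM (log2 -1.78 ± 0.12, adjusted p = 2.24e-15) in srt1-4 and to 86.3 ± 15 CPM in srt1x2. The photosynthesis list had 9 of 29 measured genes lower, as many as adjusted over the list alone in srt1-4 (camera, adjusted p = 0.0134, and adjusted p = 0.971 with an estimated correlation). In srt1x2 it had 1 of 29 measured genes higher and 13 lower, as many as adjusted over the list alone (adjusted p = 0.00217, and adjusted p = 0.938 with an estimated correlation). Catalase CAT2 (AT4G35090) fell from 1101 ± 55.3 to 379 ± 21.3 CPM (log2 -1.54 ± 0.13, adjusted p = 6.87e-13) in srt1-4. By contrast, CAT3 (AT1G20620), the catalase of the night, rose from 1394 ± 262 to 3096 ± 155 CPM (log2 1.15 ± 0.15, adjusted p = 1.05e-07).

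Some hormone genes differed too at ZT6. EIN3, of ethylene signalling, rose from 99.6 ± 12 to 194 ± 3.87 CPM (log2 0.96 ± 0.09, adjusted p = 5.14e-11) in srt1-4. In srt1x2 it rose from 99.6 ± 12 to 183 ± 7.63 CPM (log2 0.88 ± 0.09, adjusted p = 4.82e-10). The ethylene list had 10 of 19 measured genes higher and 2 lower, as many as adjusted over the list alone in srt1-4 (camera, adjusted p = 0.0189, and adjusted p = 0.938 with an estimated correlation). For srt1x2 this was 11 of 19 measured genes higher and 1 lower, or 11 higher and 2 lower adjusted over the list alone (adjusted p = 0.00752, and adjusted p = 0.938 with an estimated correlation). The jasmonate gene AOS (AT5G42650) fell from 218 ± 43.3 to 60.9 ± 12.5 CPM (log2 -1.85 ± 0.20, adjusted p = 1.44e-09) in srt1x2. There the jasmonate list had 2 of 25 measured genes higher and 13 lower, as many as adjusted over the list alone (camera, adjusted p = 0.0103, and adjusted p = 0.938 with an estimated correlation). In srt1-4 the phosphate starvation list was lower, with 4 of 9 measured genes lower, as many as adjusted over the list alone (camera, adjusted p = 0.0409, and adjusted p = 0.938 with an estimated correlation), SPX1 falling to 5.05 ± 0.566 CPM. The ethylene list and the phosphate starvation list lost the call in 1 or more of the fits without Col-0 replicate 1 (adjusted p up to 0.102) or without srt1-4 replicate 1 (0.0553).

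Among genes of NAD metabolism at ZT6, the transporter NDT1 fell from 33.8 ± 3.18 to 6.7 ± 1.42 CPM (log2 -2.32 ± 0.12, adjusted p = 2.31e-18) in srt1-4. In srt1x2 it fell to 7.22 ± 1.47 CPM (log2 -2.21 ± 0.12, adjusted p = 9.04e-18). NUDT19 (AT5G20070), a Nudix hydrolase gene, fell from 76.1 ± 4.31 to 21.1 ± 1.21 CPM (log2 -1.85 ± 0.09, adjusted p = 6.71e-19) in srt1-4 and to 20.8 ± 2.02 CPM in srt1x2. The NAD list as a set was not called, with 2 of 19 measured genes higher and 5 lower, as many as adjusted over the list alone in srt1-4 (camera, adjusted p = 0.195, and adjusted p = 0.938 with an estimated correlation). For srt1x2 it had 1 of 19 measured genes higher and 6 lower, as many as adjusted over the list alone (adjusted p = 0.108, and adjusted p = 0.938 with an estimated correlation). Of the DNA damage genes, XRCC1 (AT1G80420) rose from 14.8 ± 1.15 to 37.9 ± 1.78 CPM (log2 1.35 ± 0.16, adjusted p = 9.99e-09) in srt1-4. In total 7540 genes changed in srt1-4, 3642 higher and 3898 lower. In srt1x2 it was 7350, 3485 higher and 3865 lower. The shared part was 2889 genes higher and 3181 lower in both, and srt1x2 and srt1-4 differed from each other in 30 genes.

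The ZT6 effects of srt1-4 and srt1x2 were set against those at ZT18 by the interaction test. The light-signalling gene SPA3 (AT3G15354), which shares reads with another locus, had a log2 difference between the times of 2.86 ± 0.15 in srt1-4 (adjusted p = 7.49e-17) and 2.92 ± 0.16 in srt1x2 (adjusted p = 1.48e-16). For NDT1 it was 2.64 ± 0.16 in srt1-4 (adjusted p = 9.93e-16), and for the dormancy-associated DYL1 (AT1G28330) it was -4.44 ± 0.25 and -4.38 ± 0.25 (adjusted p = 1.94e-16 and 5.07e-16). The effect differed between the times in 5145 genes of srt1-4 and 5115 of srt1x2. Across genes, which are not independent replicates, the log2 fold changes at ZT6 and ZT18 had r = 0.00133 in srt1-4 and r = -0.00763 in srt1x2.

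At ZT18 the libraries labelled srt1-4 stood out by genes next to SRT1 itself. Of 23 tested genes in a run from SVL1 (AT5G55480) to AT5G55740, a stretch picked after its values were seen, 20 were lower at ZT6 (median log2 -1.18, quartiles -1.60 and -0.75) and 18 at ZT18 (median -0.96, quartiles -1.04 and -0.83). Within the run BAM4 (AT5G55700) was higher at ZT6 (log2 0.60, adjusted p = 0.00159, beside 1.5 in srt1x2) and lower at ZT18 (log2 -0.97, adjusted p = 8.3e-05). In srt1x2 the median of the same genes was -0.13 at ZT6 and -0.04 at ZT18, and in srt2-1 it was -0.01 and -0.02. NHX3 (AT5G55470), a sodium and proton exchanger gene next to SVL1 and outside the run, rose from 3.9 ± 0.162 to 13.3 ± 0.435 CPM (log2 1.77 ± 0.19, adjusted p = 4.95e-10) at ZT6. At ZT18 it rose from 2.94 ± 0.281 to 8.33 ± 0.731 CPM (log2 1.51 ± 0.19, adjusted p = 1.17e-06). Elsewhere, GI fell from 1.92 ± 0.743 to 0.236 ± 0.134 CPM (log2 -2.87 ± 0.46, adjusted p = 0.000122). CCA1 rose from 7.74 ± 0.112 to 19 ± 9.21 CPM (log2 1.29 ± 0.25, adjusted p = 0.00206) at ZT18. ICS1 (AT1G74710), of salicylic acid synthesis, rose from 10.5 ± 1.24 to 19.1 ± 9.03 CPM (log2 0.85 ± 0.22, adjusted p = 0.0344). The list for salicylic acid and immunity had 2 of 29 measured genes higher, or 4 higher adjusted over the list alone (camera, adjusted p = 0.00176, and adjusted p = 0.938 with an estimated correlation). GI, CCA1, ICS1 and the salicylic acid and immunity list lost the call in 1 or more of the fits without Col-0 replicate 1 (adjusted p up to 0.0862), replicate 2 (0.111) or replicate 3 (0.0949) or without srt1-4 replicate 1 (0.279). The same held for 1 or more of these calls with only the groups compared fitted (0.372) or with unique counts (0.578). Replicate 1 of srt1-4 at ZT18 stood apart from replicates 2 and 3, with a chi-square per degree of freedom of 15.2 and 15.2 against 2.87 between those.

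**Figure D4:**
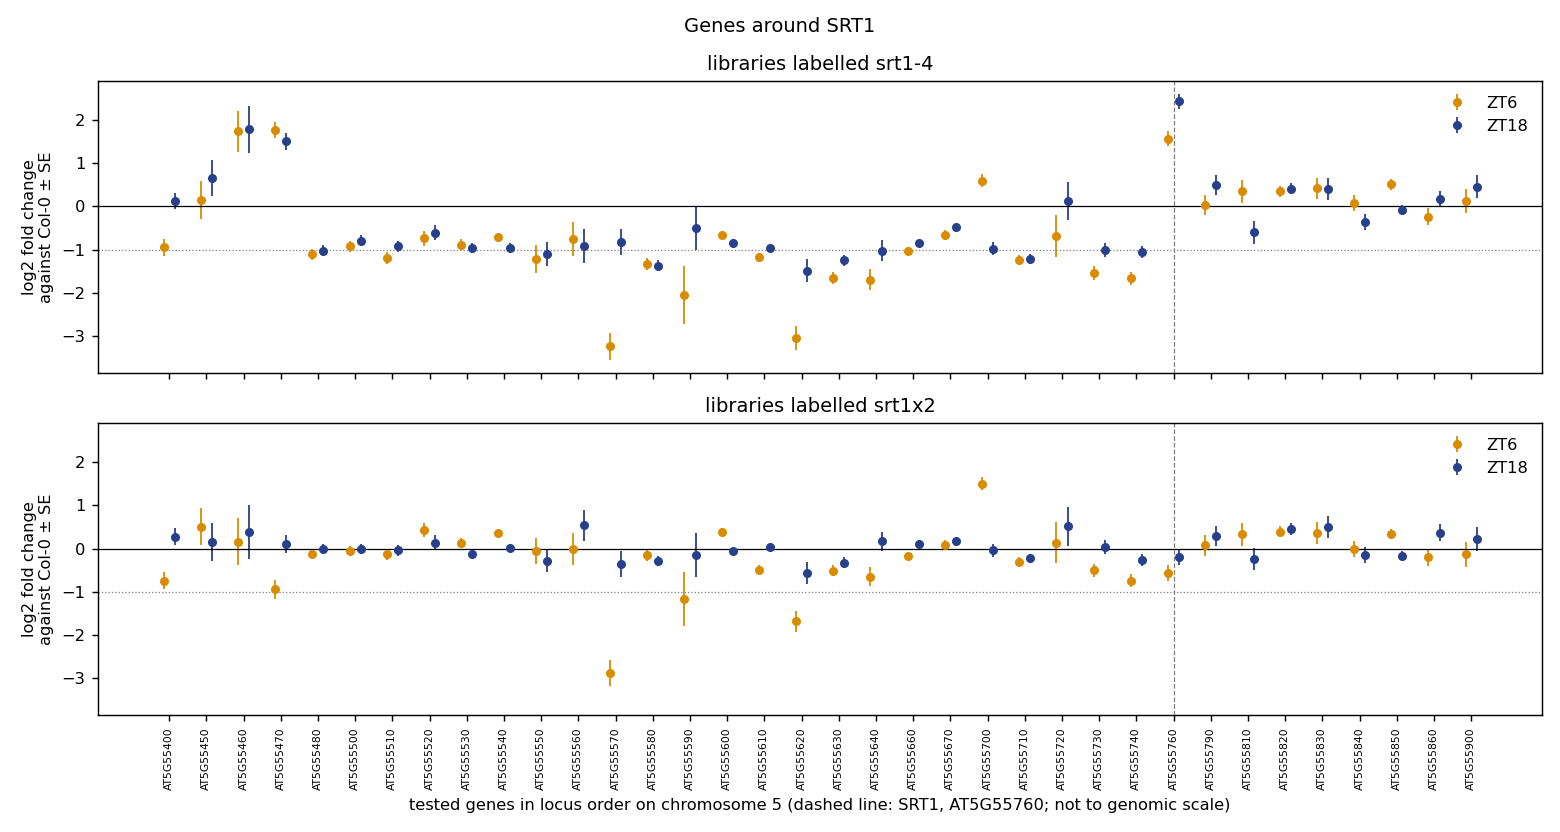
Log2 fold change against Col-0 with SE of tested genes around SRT1 in locus order (not to scale) in the libraries labelled srt1-4 and srt1x2, at ZT6 and ZT18 with 3 libraries per group. The run of 23 genes beside SRT1 (dashed line) has medians of -1.18 and -0.96 in srt1-4, near the dotted line at -1, and of -0.13 and -0.04 in srt1x2.

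Photosynthesis genes were lower as a set in srt1-4 at ZT18, with 2 of 29 measured genes lower, or 5 lower adjusted over the list alone (camera, adjusted p = 0.00284, and adjusted p = 0.938 with an estimated correlation). GUN4 fell from 213 ± 15.4 to 153 ± 20.7 CPM (log2 -0.47 ± 0.11, adjusted p = 0.0197). Plastid-encoded genes had 2 of 44 measured genes lower, or 3 lower adjusted over the list alone (adjusted p = 0.00156, and adjusted p = 0.938 with an estimated correlation). In all 318 genes changed at ZT18, 93 higher and 225 lower. The count was 111 without Col-0 replicate 1, and 144 and 137 without srt1-4 replicates 2 and 3, 17 with only the groups compared fitted and 1311 with other mutants in place of Col-0. Over both times 135 genes changed the same way, 39 higher and 96 lower, against 17.5 and 45.2 for independent calls, and 54 changed in opposite directions. The number of genes changed the same way was 60 without Col-0 ZT18 replicate 1, and 72 and 72 without srt1-4 ZT18 replicates 2 and 3, 16 with only the groups compared fitted and 692 with other mutants in place of Col-0. The photosynthesis list and GUN4 lost the call in 1 or more of the fits without Col-0 replicate 3 (adjusted p up to 0.0774) or without srt1-4 replicate 2 (0.0923) or replicate 3 (0.164). Such losses occurred with only the groups compared fitted (0.27) too.

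In srt2-1 at ZT6 the low-sugar gene BT2 rose from 15.1 ± 6.49 to 123 ± 21.9 CPM (log2 3.04 ± 0.28, adjusted p = 2.3e-09). SEN5 rose from 133 ± 23.9 to 417 ± 51 CPM (log2 1.64 ± 0.23, adjusted p = 1.04e-05). DIN10 rose from 178 ± 45.7 to 428 ± 53.9 CPM (log2 1.26 ± 0.24, adjusted p = 0.00137). In the indole glucosinolate pathway MYB51 (AT1G18570) rose from 5.35 ± 2.06 to 12.2 ± 1.68 CPM (log2 1.21 ± 0.24, adjusted p = 0.00197). MYB34 fell from 44.3 ± 2.68 to 23.65 ± 3.18 CPM (log2 -0.90 ± 0.16, adjusted p = 0.000577). NDT1 fell from 33.8 ± 3.18 to 23.9 ± 0.716 CPM (log2 -0.49 ± 0.10, adjusted p = 0.00403). FLC rose from 1.44 ± 0.445 to 5.35 ± 0.849 CPM (log2 1.88 ± 0.30, adjusted p = 0.000167). The list for abscisic acid, drought and cold was lower as a set, median log2 -0.73, with 1 of 27 measured genes lower, or 12 lower adjusted over the list alone (camera, adjusted p = 0.00156, and adjusted p = 0.938 with an estimated correlation). Plastid-encoded genes were lower, median log2 -0.29, with 0 of 44 measured genes past the threshold with edgeR or DESeq2, 1 higher and 6 lower at an unadjusted p under 0.05 and 0 adjusted over the list alone (adjusted p = 0.0169, and adjusted p = 0.938 with an estimated correlation). In all 761 genes changed, 396 higher and 365 lower. The number was 498 and 212 without Col-0 replicates 2 and 3, and 391 and 425 without srt2-1 replicates 2 and 3. NDT1 and the plastid-encoded list lost the call in 1 or more of the fits without Col-0 replicate 3 (adjusted p up to 0.395) or without srt2-1 replicate 2 (0.126).

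By night in srt2-1 the light-harvesting gene LHCB6 (AT1G15820) rose from 545 ± 148 to 1118 ± 35 CPM (log2 1.04 ± 0.22, adjusted p = 0.00627). LHCB3 rose from 212 ± 36.1 to 464 ± 46.7 CPM (log2 1.13 ± 0.25, adjusted p = 0.00727). The photosynthesis list had 11 of 29 measured genes higher, or 16 higher adjusted over the list alone (camera, adjusted p = 6.38e-10, and adjusted p = 0.938 with an estimated correlation). GI fell from 1.92 ± 0.743 to 0.343 ± 0.395 CPM (log2 -2.53 ± 0.47, adjusted p = 0.00149). PRR7 fell from 2.29 ± 0.813 to 0.355 ± 0.214 CPM (log2 -2.50 ± 0.49, adjusted p = 0.00274). The sugar transporter gene STP1 fell from 289 ± 95.6 to 160.3 ± 7.97 CPM (log2 -0.85 ± 0.21, adjusted p = 0.0176). The jasmonate list had 2 of 25 measured genes lower, or 6 lower adjusted over the list alone (adjusted p = 0.0123, and adjusted p = 0.938 with an estimated correlation). In all 836 genes changed, 365 higher and 471 lower. That number was 237, 171 and 1290 without Col-0 replicates 1, 2 and 3, and 245, 482 and 289 without srt2-1 replicates 1, 2 and 3, and 119 with only the groups compared fitted. With other mutants in place of Col-0 it was 20. LHCB6, LHCB3, PRR7, STP1 and the jasmonate list lost the call in 1 or more of the fits without Col-0 replicate 1 (adjusted p up to 0.118) or replicate 2 (0.215) or without srt2-1 replicate 1 (0.0582) or replicate 3 (0.0763). Further losses came with only the groups compared fitted (0.0665).

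Few genes of srt2-1 changed the same way by day and night, 25 in all, 14 higher and 11 lower, against 7.45 and 8.86 for independent calls, and 64 changed in opposite directions. The count of the same way was 16 and 16 without Col-0 ZT18 replicates 1 and 2, and 16 without srt2-1 ZT18 replicate 1, 14 with only the groups compared fitted and 6 with other mutants in place of Col-0. TPS8 and TPS11 had log2 differences between the times of -1.88 ± 0.19 and -2.41 ± 0.26 (adjusted p = 1.23e-07 and 3.28e-07), and BT2 of -3.18 ± 0.37 (adjusted p = 5.29e-07). The interaction test gave 1488 genes, 620 with a higher and 868 with a lower log2 fold change at ZT18. This number was 675 without Col-0 ZT6 replicate 3, 854 without Col-0 ZT18 replicate 2, and 880 without srt2-1 ZT18 replicate 1.

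At ZT18 the libraries labelled srt1x2 had more transcript of the flowering repressors MAF5 (AT5G65080) and MAF4 (AT5G65070), which share reads with each other. MAF5 rose from 0.724 ± 0.606 to 7.4 ± 0.875 CPM (log2 3.32 ± 0.52, adjusted p = 0.000164). MAF4 rose from 1.85 ± 0.325 to 7.55 ± 1.46 CPM (log2 2.01 ± 0.30, adjusted p = 6.55e-05). Both also rose at ZT6 (log2 2.39 ± 0.47, adjusted p = 8.0e-05 and log2 1.86 ± 0.30, adjusted p = 4.09e-06). FLC rose from 1.95 ± 0.668 to 6.0 ± 0.61 CPM (log2 1.59 ± 0.27, adjusted p = 0.000699). The dawn gene CCA1 rose from 7.74 ± 0.112 to 30.1 ± 8.43 CPM (log2 1.96 ± 0.24, adjusted p = 1.66e-06). GI fell from 1.92 ± 0.743 to 0.285 ± 0.0951 CPM (log2 -2.60 ± 0.47, adjusted p = 0.00132). The list for salicylic acid and immunity had 1 of 29 measured genes higher, or 6 higher and 1 lower adjusted over the list alone (camera, adjusted p = 0.0038, and adjusted p = 0.938 with an estimated correlation). Photosynthesis genes had 1 of 29 measured genes higher, or 8 higher adjusted over the list alone (adjusted p = 0.024, and adjusted p = 0.971 with an estimated correlation). In all 282 genes changed, 108 higher and 174 lower. The number was 75, 103 and 457 without Col-0 replicates 1, 2 and 3, and 162 and 81 without srt1x2 replicates 2 and 3, and 13 with only the groups compared fitted. FLC, the salicylic acid and immunity list and the photosynthesis list lost the call in 1 or more of the fits without Col-0 replicate 1 (adjusted p up to 0.0846) or replicate 2 (0.0845) or without srt1x2 replicate 1 (0.626) or replicate 3 (0.0913). Calls were also lost with only the groups compared fitted (0.162). Without srt1x2 replicate 1 the photosynthesis list also turned from higher to lower. That library stood apart from replicates 2 and 3, with a chi-square per degree of freedom of 11.6 and 9.87 against 4.46 between those.

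Over both times 104 genes of the libraries labelled srt1x2 changed the same way, 36 higher and 68 lower, against 19.4 and 34.7 for independent calls, and 54 in opposite directions. MAF4, MAF5, AT4G29990 and AT4G03230 were among the former. Their number was 37 and 55 without Col-0 ZT18 replicates 1 and 2, and 61 and 40 without srt1x2 ZT18 replicates 2 and 3, and 11 with only the groups compared fitted.

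The cell division list was higher as a set at ZT18 in parp1-2, parp1x2x3, srt1-4 and srt1x2, with median log2 values of 0.25, 0.16, 0.19 and 0.20 over 13 genes (camera, adjusted p = 0.0038, 0.00695, 0.0356 and 0.0141, and adjusted p = 0.938 with an estimated correlation in each). In each, 0 of the 13 genes passed the threshold with edgeR or DESeq2, and 2, 2, 2 and 4 had an unadjusted p under 0.05. Adjusted over the list alone, 2 passed in srt1-4 and 0 in the others. The cell division list lost its call without Col-0 replicate 1 (adjusted p up to 0.0528) or replicate 2 (0.58), without parp1x2x3 replicate 3 (0.0707) or without srt1-4 replicate 2 (0.26) or replicate 3 (0.193).

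Profiles labelled as combined and single mutants were compared across all genes. As srt1x2 lacked the SRT1 rise and lower ZT18 run of srt1-4, r with srt1-4 cannot be read as a shared allele. Genes are not independent replicates and pairs share Col-0, so values of simulated unchanged groups are given. At ZT6 the log2 fold changes of srt1x2 and srt1-4 had r = 0.928 (simulated 0.498) and covariance 0.503 (simulated 0.0362), and those of srt1x2 and srt2-1 had r = 0.419 (0.5) and covariance 0.117 (0.0369). They shared 254 genes higher and 246 lower (71.1 and 72.7 for independent calls). The profile of parp1x2x3 had r = 0.435 with parp1-2 (simulated 0.493), 0.633 with parp2-1 (0.496) and 0.654 with parp3-1 (0.498) at ZT6, with covariances of 0.0501, 0.0795 and 0.0817 (simulated 0.0370, 0.0371 and 0.0371). With parp3-1 it shared 129 genes higher and 33 lower (4.34 and 0.560 for independent calls). At ZT18 r was 0.678 with parp1-2 (simulated 0.510), 0.621 with parp2-1 (0.512) and 0.633 with parp3-1 (0.521). There srt1x2 had r = 0.762 with srt1-4 (0.526) and 0.635 with srt2-1 (0.511). Unchanged simulated groups have few calls to share, so their 0 tests nothing, and each excess may partly reflect shared Col-0.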

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

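The tests on the ZT6 profile of srt1-4 and srt1x2, on genes near the mutated loci, on Col-0 without srt1-4 and srt1x2, the fits of only the groups compared in this part, and the regroupings of the 14 mutant comparisons, of Col-0 and of the 4 parp interactions were chosen only after the result was seen, and the other tests in this part before it.

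The effect of each mutant was compared between ZT18 and ZT6 by an interaction test, and in all 7 mutants it differed for some genes. Their number was 13 in parp1-2, 60 in parp2-1, 61 in parp3-1, 537 in parp1x2x3, 5145 in srt1-4, 1488 in srt2-1 and 5115 in srt1x2. Regrouping the 12 libraries in 21 ways, with all 48 libraries fitted for the real and the other groupings, gave at most 21, 39, 56, 233, 5090, 162 and 4184 genes in this order. For parp1-2, 2 of the 21 groupings gave as many genes. For the 6 others 1 did, the lowest possible share, for parp3-1 and srt1-4 by a small margin. The regrouping swaps labels within a time, so it tests any genotype effect and cannot exclude a chance interaction. With only the 12 libraries fitted, these 6 had 7, 29, 219, 4290, 1012 and 3967 genes against at most 2, 2, 148, 3968, 11 and 2954, again 1 of 21. The high values of srt1-4 and srt1x2 came from groupings that left the ZT6 groups as labelled. For genes changed the same way at both times, the real numbers of 23, 19, 25, 28, 135, 25 and 104 stood against at most 0, 0, 0, 2, 0, 0 and 0 in other groupings. Such an overlap needs calls at both times, and most other splits of 3 with 3 libraries called few genes at 1 time, so numbers near 0 follow from that and say nothing of agreement between the times beyond independent calls. In srt2-1 the 25 genes stood against 7.45 and 8.86 for independent calls, with 64 in opposite directions.

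For comparisons of 3 with 3 libraries, 10 splits are too few for a share under 0.05. At ZT6 the real numbers of 34, 61, 208, 748, 7540, 761 and 7350 genes (parp1-2, parp2-1, parp3-1, parp1x2x3, srt1-4, srt2-1, srt1x2) stood against at most 1, 0, 2, 0, 0, 7 and 0 in other splits. At ZT18 562, 147, 84, 68, 836 and 282 (without srt1-4) stood against at most 36, 2, 1, 0, 0 and 13, and the 6949 genes of Col-0 between the times against 7. For srt1-4 at ZT18 another split gave 2289 genes against the real 318, so that 2 of the 10 splits gave as many. It set Col-0 replicates 1 and 2 with srt1-4 replicate 1 apart, and a count several times the real one points to a structure of the samples other than the genotype.

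The ZT6 profile of the libraries labelled srt1-4 and srt1x2 was weighed against ZT18 libraries under a ZT6 label. Over the 200 genes that differ most between the times in the other mutants, ZT6 of the others lies at 0 and ZT18 at 1. The srt1-4 libraries had a median of 0.272 (quartiles 0.0104 and 0.698) and those of srt1x2 of 0.374 (0.0741 and 0.813), against 1.03 in Col-0 at ZT18, which argues against such a mix-up. A higher SRT1 level or the lower run beside it does not explain both. In srt1x2 SRT1 was at log2 -0.56 ± 0.19 and the run's median at -0.13. Absence of the SRT2 transcript does not explain both either. SRT2 had 13.5 ± 0.379 CPM in srt1-4 at ZT6, and srt2-1, which lacks it, lay at 0.0458 (quartiles 0.0106 and 0.0965). Collection at a later clock time or in another light state, which predicts lower morning and higher evening clock genes, matched 15 of 17 clock genes in each genotype. A change of the clock by the genotype predicts the same, so the clock genes cannot tell these apart.

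The 13 genes shared by at least 6 of the 7 mutants at both times could reflect chance values of the shared Col-0 libraries. The 10 simulated sets gave at most 0, but unchanged groups call few genes, so this cannot decide. With only the groups compared fitted, 3 of the 13 stayed shared. A candidate explanation is that the Col-0 seedlings differ from all mutant lines for a reason other than the mutations, such as another seed stock. It predicts that more genes set Col-0 apart from the mean of the other genotypes at both times than set apart the lines parp1-2, parp2-1, parp3-1, parp1x2x3 and srt2-1. The number was 91 for Col-0, 228 for parp1-2 and 7, 15, 9 and 31 for the others. For srt1-4 and srt1x2, left out of that prediction for their ZT6 profile, it was 342 and 22. With those 2 genotypes left out of the comparison altogether, it was 49 for Col-0 against 10, 6, 13, 7 and 7 for the same 5 lines, so Col-0 then stood apart most. A real effect common to all 7 mutants predicts the same pattern, and the 2 cannot be told apart, because Col-0 is the only reference.

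Genes changed at both times were also weighed for their position. Of 267 such calls, gene by mutant, not shared by the mutants, 22 (21 distinct genes) lay within 50 tested genes of the labelled loci, against 1.99 when the loci were rotated along the genome (permutation test by rotation, p = 0.0051), and 19 of the 22 belonged to srt1-4 (adjusted p = 0.0126). The 1 gene each of parp1-2, parp1x2x3 and srt1x2 gave adjusted p = 0.195, 0.374 and 1. Variants linked to the mutated loci are a candidate explanation for srt1-4. Loss of 1 copy of a segment beside SRT1 predicts a fall of about 1 log2 unit for all genes in it. The 6 genes of the run outside those changed the same way at both times had a median of -0.71 at ZT18, and -0.61 without BAM4, called at both times in opposite directions. This is consistent with the loss, as a hypothesis found and tested on the same data. The loss alone does not explain the higher BAM4 at ZT6 (log2 0.60) or the deeper falls of AT5G55570 (-3.24) and AT5G55620 (-3.04), which were at 1.5, -2.89 and -1.68 in srt1x2. An effect of SRT1 on the expression of its neighbours was not tested and stays open.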

How the results depend on the processing

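The reference of other mutants and the fit without the srt1-4 and srt1x2 ZT6 libraries were chosen after the result was seen. Of 638 values of named genes, 638 kept direction and call under RLE scaling, 625 with no low-count filter and 622 with a replicate block (parp1-2 at ZT6, 32 genes). Samples share only a replicate number (median same-number r of 0.0308 at ZT6 and -0.0221 at ZT18, with 20 of 84 pairs over 0.1 at each time). Yet 16 of 24 libraries at ZT6 and 7 of 24 at ZT18 correlated best with their own number, a hint of pairing at ZT6 from the data alone. DESeq2 kept 572 of 579, unique counts 522 of 557 and a fit of only the groups compared 447 of 608. Without srt1-4 and srt1x2 at ZT6 it was 427 of 439, and without 1 library 3465 of 4038. Values absent from totals under 638 were not counted as lost. Reversed were NADK2 (AT1G21640) with unique counts in parp1x2x3 at ZT6 (-0.0870) and srt1x2 at ZT18 (0.0878), and the photosynthesis list of srt1x2 at ZT18 without srt1x2 replicate 1 (adjusted p = 0.626, against 1.84e-06 without replicate 2). The cause was not tested. In the order parp1-2, parp2-1, parp3-1, parp1x2x3, the ZT6 counts fell to 19, 27, 100 and 348 with only the groups compared, where fewer samples estimate the spread. At ZT18 they fell to 13, 8, 19, 20, 17, 119 and 13 (then srt1-4, srt2-1, srt1x2), the parp interactions to 0, 7, 29 and 219, and the counts at both times to 9, 6, 15, 14, 16, 14 and 11. The 0 stands beside 1998 genes at an unadjusted p under 0.05 with edgeR there. DESeq2 raised parp1-2 and parp2-1 at ZT6 to 53 and 94, the 4 parp lines at ZT18 to 967, 236, 130 and 108, and the interactions of parp1-2, parp2-1 and parp3-1 to 73, 261 and 210. Unique counts gave 40 for parp2-1 at ZT6 and 8 and 39 for the interactions of parp1-2 and parp2-1. Against the other mutants in place of Col-0, the counts were 1095, 5, 20 and 110 for the parp lines at ZT6, 82, 10, 36, 8, 1311 and 20 for these, srt1-4 and srt2-1 at ZT18, and 10, 5, 12, 8, 692 and 6 at both times. With an estimated correlation 0 of 38 list calls in mutants and 0 of 5 in Col-0 stayed, with 11 and 3 lists at an unadjusted p under 0.05. At an average log2 CPM of at least 3, r moved to 0.373 and 0.745 for parp1x2x3 with parp1-2 and parp3-1 and 0.964 for srt1x2 with srt1-4 at ZT6, and between the times to 0.253, 0.179, 0.0487 and -0.0647 for parp1-2, parp3-1, srt1-4 and srt2-1. Leaving out 1 library, the ZT6 counts ranged over 20 to 63, 24 to 59, 55 to 293, 269 to 777, 6482 to 6824, 212 to 710 and 6310 to 7024 (parp1-2, parp2-1, parp3-1, parp1x2x3, srt1-4, srt2-1, srt1x2). The ZT18 counts ranged over 41 to 1427, 24 to 147, 34 to 88, 31 to 93, 111 to 466, 171 to 1290 and 75 to 457, and Col-0 between the times over 5685 to 6982. The interactions ranged over 2 to 170, 4 to 86, 18 to 96, 204 to 656, 4307 to 5701, 675 to 1621 and 4324 to 5466, the counts at both times over 16 to 23, 14 to 20, 21 to 25, 19 to 26, 60 to 168, 16 to 29 and 37 to 141, and the list calls over 34 to 47 and, in Col-0, 4 to 6. The cause was not tested beyond the smaller number of samples.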

Other observations

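All tests of a smaller copy of the srt1-4 profile in other mutants were chosen only after the result was seen. SUR1 (AT2G20610), of indole glucosinolate synthesis, fell from 142 ± 10.4 to 45.6 ± 2.63 CPM (log2 -1.64 ± 0.12, adjusted p = 1.32e-14) in srt1-4 at ZT6, and MYB34 fell to 11.6 ± 2.66 CPM in srt1-4 and 9.88 ± 3.12 CPM in srt1x2 from 44.3 ± 2.68 CPM in Col-0. The flowering gene SVP (AT2G22540) fell from 85.5 ± 9.21 to 49.2 ± 1.83 CPM (log2 -0.79 ± 0.11, adjusted p = 4.42e-07) in srt1-4 and to 45.1 ± 5.93 CPM in srt1x2. RCD1 (AT1G32230), which has a domain related to the polymerases, rose from 153 ± 1.65 to 217 ± 2.68 CPM (log2 0.50 ± 0.08, adjusted p = 1.14e-06) in srt1-4 and to 207 ± 8.32 CPM in srt1x2. COR27 (AT5G42900), which links cold and the clock, rose from 1.69 ± 0.913 to 65.4 ± 16.2 CPM (log2 5.27 ± 0.35, adjusted p = 1.71e-15) in srt1x2, as did the auxin gene IAA29 (AT4G32280) from 0.763 ± 0.0811 to 49.4 ± 14.7 CPM (log2 5.98 ± 0.40, adjusted p = 4.25e-15).

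SEN5, raised in the libraries labelled srt1-4 and srt1x2 at ZT6, was also raised, by less, in parp3-1, parp1x2x3 and srt2-1. The starvation list had a camera adjusted p = 0.00627 in parp1x2x3 and 0.457 in parp3-1 and in srt2-1. With an estimated correlation these were 0.938, 0.971 and 0.971, and the lines were not tested against each other. The hypothesis that the other mutants carry a smaller copy of the srt1-4 profile was tested with the slope of each mutant's log2 fold changes on those of srt1-4 across genes, each computed against separate Col-0 libraries. The mean slope over the 3 ways to set 1 Col-0 library apart was 0.0725 in parp2-1 (0.0691 to 0.0762), 0.115 in parp3-1 (0.0971 to 0.125), 0.161 in parp1x2x3 (0.146 to 0.172) and 0.121 in srt2-1 (0.106 to 0.134), above 0.05 in each way. In parp1-2 it was 0.0360 (0.0257 to 0.0531), which leaves this line open. Genotype, collection or a Col-0 group standing apart could give such slopes and were not separated. The 3 ways share mutant libraries.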
